A study of Danio rerio with 14 samples.

How the data were processed

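Poly-A RNA from the intestine of zebrafish was sequenced in 14 libraries. Per the labels, 6 libraries came from fish carrying a transgene, Tg(Xla.Eef1a1:Cau.Asip1)iim04, and 8 from fish labelled Tubingen, taken here as wild-type. The genotype label of the transgenic libraries names only the transgene, so a difference of background cannot be told apart from its effect. By the usual naming of such constructs, the transgene places goldfish Asip1, the gene of agouti signalling protein, under the frog Eef1a1 promoter. Each title ends in the letter M or H, which the labels do not explain. The letter splits both genotypes evenly, into 3 transgenic and 4 wild-type libraries each, so 4 groups were kept: transgenic M, transgenic H, wild-type M and wild-type H. Replicate numbers are those of the titles. The labels do not say that the libraries came from separate fish, so the p-values measure the spread between these samples, which may be technical in part.

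Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a stranded kit after selection of polyadenylated RNA on poly-T beads. Per the submitters' processing notes, FastQC, STAR 2.7.3a, featureCounts 1.6.3 and edgeR were used. The notes list the genome builds GRCm38.p6, mm10 and GRCz11 without a role, and the strand setting of the counting is not given in the sources used here. All 32520 gene identifiers in the table are zebrafish Ensembl identifiers. The deposited table holds the authors' raw read counts per gene, which are whole numbers and are not normalized. The FPKM values deposited beside them by the authors are those same counts divided by gene length and by the column total, so they carry no independent information. Counting may split reads between near-identical paralogs, and genes of expanded families named here (class I major histocompatibility genes, elastases, glucuronosyltransferases, finTRIM and vitellogenin genes) are uncertain in that respect. No row of the table names the goldfish transgene.

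Total counts ranged from 9847910 to 14091791 per library. Symbols were taken from the supplied reference table, which gave one to 29201 of the identifiers. Of 893 names in the gene lists, 839 were matched, 649 through a current or older zebrafish symbol and 190 through a human-style symbol. Where several zebrafish genes share a human-style symbol, the identifier is printed. Chromosomes were taken from a gene table of the GRCz12tu assembly, whose build differs from that of the notes. A gene without its own place took the chromosome on which the nearest placed rows of the count table agreed. Of neighbouring placed rows, 97.6% were on the same chromosome. Gene neighbourhood was taken from the order of the count table.

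Tests on counts used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 4 groups, which left 18619, and libraries were scaled with TMM factors. One mean per group was fitted over all 14 libraries (glmQLFit, glmQLFTest), so that the groups shared 1 estimate of the spread. There were 5 gene-wise comparisons: genotype averaged over the letters, genotype within the M libraries, genotype within the H libraries, the difference between those effects, and H against M averaged over genotypes. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Positive log2 fold changes mean higher in transgenic libraries, or higher in H for the last comparison. The SE printed with a log2 fold change is its absolute value divided by the square root of the F statistic. It restates the test and is not a separate estimate of precision. CPM values were computed with the cpm function of edgeR on TMM-scaled totals, and log2 CPM used a prior count of 2. Where a group had 0 counts in all of its libraries, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with its exact 95% interval. These intervals cover counting error only.

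Gene lists were tested with camera (limma 3.58.1) on log2 CPM with the same design, for 38 lists with at least 5 tested members, at a preset correlation between genes of 0.01. Adjusted p-values given for lists are from camera over these lists unless another test is named. The same test with a correlation estimated per list and the directional fry test were run as alternatives. As many lists were called in 52 of 100 groupings of the libraries by genotype and 35 of 100 by letter, the real one included. Chance is therefore not excluded for list calls given below.

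Designs, lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule names, for genotype, the 12 highest and 12 lowest log2 fold changes with adjusted p under 0.05, a mean of at least 5 CPM in the higher genotype, a symbol that is not a clone-type name, and the same direction in M and H. Within a letter it names 6 each way. From each list it names up to 4 passing members, or the 2 with the smallest p as values where none passes. Members of the melanocortin list that were tested are always reported. A gene named outside this rule is said to have been chosen after its values were seen. The values of 1 gene that the rule names are not reported here.

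Alternatives were other scaling factors (RLE and upper quartile), library sizes without pancreas, liver and vitellogenin genes, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in at least 6 libraries, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), pancreas or liver list means as covariates, a design with genotype or letter alone, surrogate variables (sva 3.50.0, 2 variables), each letter fitted alone, and each library left out in turn. After the data were seen, fits without the 2 libraries richest in oocyte transcripts, without the 4 libraries that held them, with the ovary list mean as a covariate, and list tests with the M libraries alone were added. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

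The scripts were tested on simulated counts drawn from the means and totals of these libraries for 18199 genes. For genotype, 6% of genes changed by a log2 fold of 1, 52% at 2, 86% at 3 and 92% at 4 were called (50 genes at each size), with 2 of 17999 unchanged genes called. Within M the shares were 0%, 28%, 62% and 74%, and within H 2%, 24%, 66% and 66%. The changed genes all had a mean of at least 1 CPM, so these shares do not cover genes below it. With no simulated effect, 0 genes were called for the difference between letters and 0 for H against M. When the 31 members of the interferon list were raised, that list had an adjusted p of 0.00262, or 0.0410 with an estimated correlation, and 0 other lists were called. Genes were drawn independently around 1 mean per gene, so differences in tissue content between libraries and correlation between genes were absent. The rates of false calls therefore do not carry over to the real counts. There, other groupings of the libraries gave up to 74 genes for genotype, 3062 within H and 24 lists by genotype. No replicate pair within a group was a duplicate. The lowest chi-square per degree of freedom over 18 pairs was 27.4.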

Results

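Gene expression was measured in the intestine of zebrafish that carried a goldfish agouti transgene and of wild-type fish, labelled Tubingen. The count table covered 14 libraries: 3 transgenic M, 3 transgenic H, 4 wild-type M and 4 wild-type H, where M and H are the letters that end the sample titles. Total counts were between 11792225 and 14091791 in the 6 transgenic libraries and between 9847910 and 13727372 in the 8 wild-type libraries. The series asks how overproduction of agouti, an antagonist of melanocortin receptors, relates to the gut barrier and to the uptake of amino acids.

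Transcripts of other tissues differed between the libraries, and mainly between the H libraries. The ovary and oocyte list, which holds egg coat and oocyte genes, had a mean log2 CPM of 9.51 in wild-type H replicate 6, 6.36 in wild-type H replicate 7, 4.98 in wild-type H replicate 8 and 3.71 in transgenic H replicate 13. In the 7 M libraries it lay between -2.35 and -1.77. These genes made up 2.49%, 0.450%, 0.113% and 0.0414% of the counts in those 4 H libraries, against at most 0.000335% in any M library. Vitellogenins, the egg yolk precursors made in the liver of egg-laying females, made up 18.2%, 7.95% and 21.0% of counts in transgenic H replicates 13, 14 and 16 and 6.18% in wild-type H replicate 8, against at most 0.00104% in the M libraries. The list of sugar transporters and brush-border hydrolases, markers of absorptive enterocytes, had a mean log2 CPM of 2.0 in wild-type H replicate 6 and 4.29 in wild-type H replicate 7, against 7.29 to 8.34 in the other 12 libraries. Exocrine pancreas transcripts ranged from 0.186% to 8.55% of counts and liver transcripts from 0.0745% to 4.60%. Counts of changed genes are therefore also given without wild-type H replicates 6 and 7, a choice made after seeing the data.

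**Figure D1:**
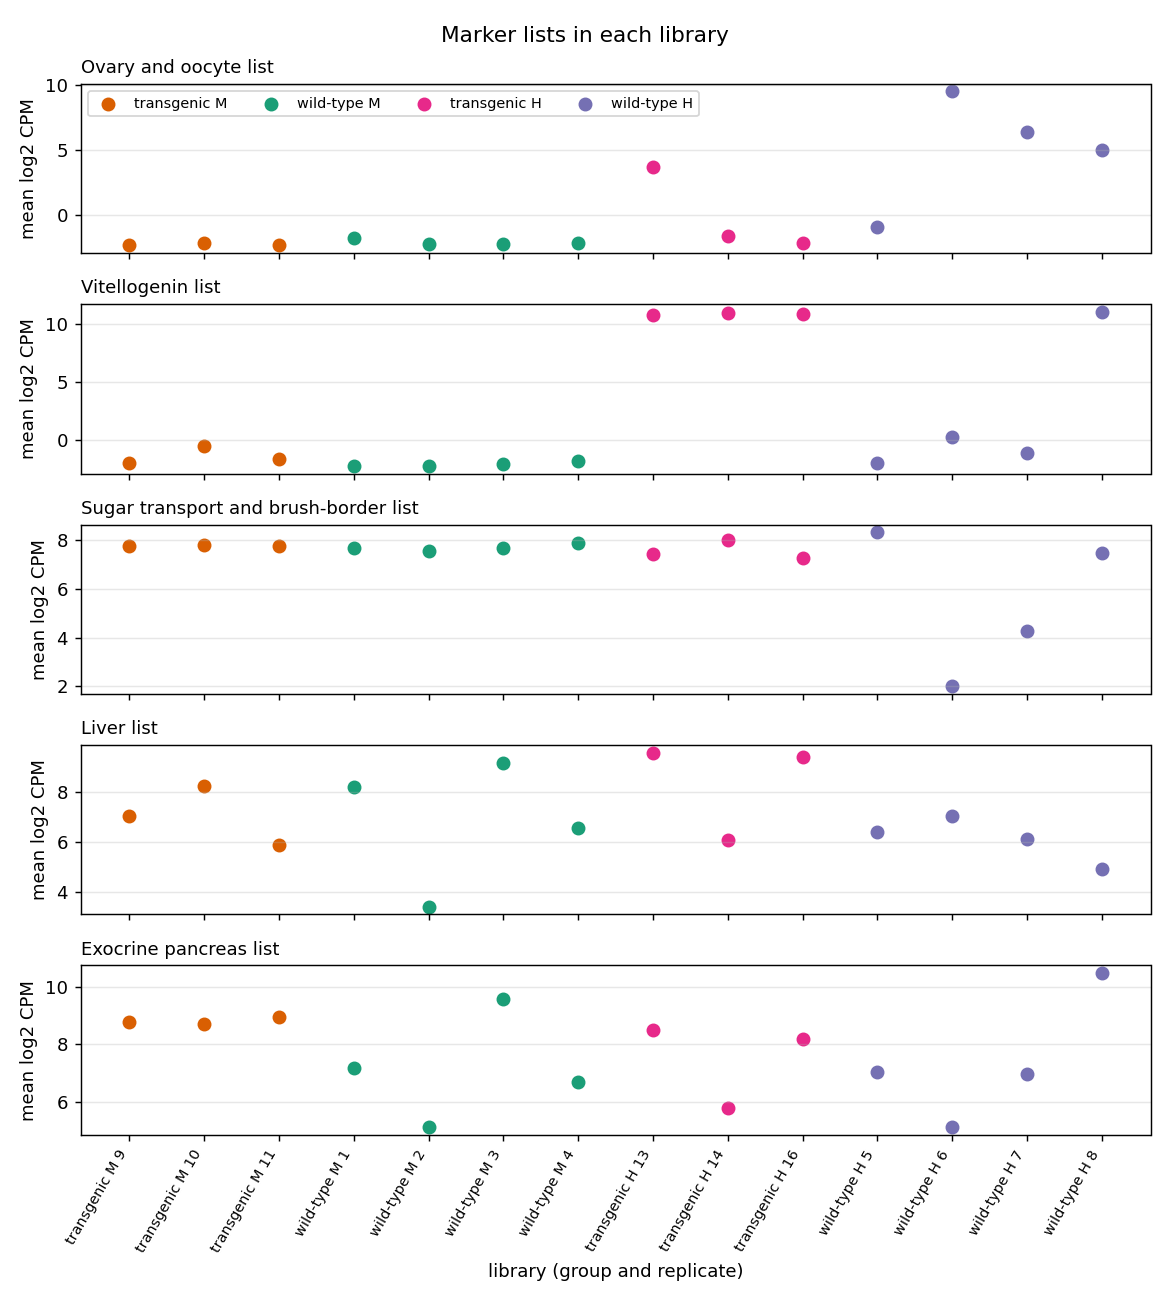
Mean log2 CPM of 5 marker lists in each of the 14 libraries, with 1 point per library, grouped by genotype and title letter. The ovary and oocyte list reached 9.51 in wild-type H replicate 6, where the brush-border list was lowest at 2.0.

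The endogenous agouti gene was barely detected. ASIP (ENSDARG00000077858), the zebrafish counterpart of the transgene's coding sequence, had 0 to 4 counts per library in the transgenic fish and 0 to 5 in the wild-type fish, 16 and 18 counts in all, and was too low to be tested. The table has no entry for the goldfish transgene, so its expression was not measured here. Of the 8 tested members of the melanocortin list, 1 passed: MGRN1 (ENSDARG00000100072), a ubiquitin ligase of the agouti pathway, fell in transgenic fish by 0.78 on the log2 scale (SE 0.19, adjusted p = 0.0352, 23.4 ± 4.36 against 40.4 ± 8.42 CPM, SD, n = 6 and 8), a call that held in 3 of the 14 fits that left out 1 library. Its paralog MGRN1 (ENSDARG00000004796) had a log2 fold change of -0.32 (adjusted p = 0.229). DESeq2 called 2 of the 8 members. Attractin (ATRN), an accessory receptor for agouti, was at 54.2 ± 8.76 against 55.7 ± 14.2 CPM, and the log2 fold changes of ATRNL1 (ENSDARG00000006420), ATRNL1 (ENSDARG00000077188), PCSK1, PCSK2 and asip2b were -0.34, 0.26, 0.09, 0.41 and 0.74, with adjusted p between 0.344 and 0.939 for these 6 genes. agrp and MC3R had 0 counts in all libraries. The other melanocortin receptors were also too low to be tested. MC1R, mc2r and MC4R had 1, 9 and 14 counts over all 14 libraries. MC5R (ENSDARG00000054946) and MC5R (ENSDARG00000031348) had 8 and 15. The list as a whole was not called (adjusted p = 0.882).

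Genotype was tested over all 14 libraries. In transgenic intestine 408 genes rose and 376 fell, 784 of 18619 tested, and 730 of them differed by at least 2-fold. Among the highest were genes nearly silent in wild-type fish. ftr80, a member of the finTRIM family of antiviral ubiquitin ligases, was at 19.8 ± 4.64 CPM (SD, n = 6) against 0 counts in all 8 wild-type libraries, at least 635-fold higher (adjusted p = 6.65e-05). ACADSB (ENSDARG00000098174), an acyl-CoA dehydrogenase of isoleucine breakdown, rose by a log2 fold change of 6.72 (SE 0.23, adjusted p = 6.47e-09), from 0.206 ± 0.0480 to 22.8 ± 3.09 CPM. ITLN1 (ENSDARG00000095082), an intelectin that binds microbial sugars, rose by 7.89 (SE 0.73, adjusted p = 7.49e-05), and KCNJ13, an inwardly rectifying potassium channel, by 5.95 (SE 0.52, adjusted p = 4.73e-05).

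A pair of class I major histocompatibility genes, which encode antigen-presenting molecules, moved in opposite directions. mhc1uba rose from 9.34 ± 5.72 to 1773 ± 1407 CPM (log2 fold change 7.60, SE 1.23, adjusted p = 0.00341), but transgenic M replicate 11 and transgenic H replicate 14 had a log2 CPM of 3.86 and 4.61, near the highest wild-type value of 4.15. The other 4 were all above 11, the highest at 11.60. In contrast, mhc1zba fell from 1513 ± 778 to 90.9 ± 23.4 CPM (log2 fold change -4.00, SE 0.60, adjusted p = 0.00229). The elastase gene cela1.5 rose by 5.92 (SE 1.19, adjusted p = 0.0128), and cela1.7 had 0 counts in all 6 transgenic libraries against 11.5 ± 12.2 CPM in wild-type fish, at least 299.7-fold lower (adjusted p = 0.00392). For cela1.5, wild-type M replicate 1 was at a log2 CPM of 3.84, above 2.43 in transgenic H replicate 14. The glucuronosyltransferase gene ugt2b5 rose by 4.99 (SE 0.42, adjusted p = 4.06e-05), and ugt2a6 was at -5.11 (SE 1.15, adjusted p = 0.0248). In transgenic H replicate 16 ugt2a6 had a log2 CPM of 3.15, inside the wild-type range of 1.29 to 5.03. The other genes that rose under the naming rule were cyp2x10.1, a cytochrome P450, at 4.62, ACKR3 (ENSDARG00000058179), a chemokine scavenger, at 5.93, cbln7 at 6.41, hnrnpa0a at 6.49 and ifi44f5 at 6.92, with adjusted p between 7.57e-05 and 0.0222. ifi44f5 had 0 counts, a log2 CPM of -2.58, in transgenic M replicate 9 and transgenic H replicate 14, and was at 1.14 in wild-type M replicate 2. hnrnpa0a was at 4.67 in wild-type H replicate 7, above 4.24 in transgenic M replicate 10. Those that fell were NPTN (ENSDARG00000103002), ADCY8, urahb, tgm5l, plekhs1.3, the galectin lgals9l4, rnasel2, linc.setd1ba, TCIM (ENSDARG00000076858) and loc100334908, at log2 fold changes from -4.44 (ADCY8) to -8.90 (loc100334908) and adjusted p between 0.000114 and 0.0363. The libraries of the genotypes overlapped for ADCY8, tgm5l, plekhs1.3 and lgals9l4. Of these 24 genes, 19 passed with each of the 14 libraries left out in turn. hnrnpa0a lost its call without wild-type M replicate 3 (adjusted p = 0.0595), and ugt2a6, ifi44f5, ADCY8 and tgm5l passed in 11, 9, 6 and 5 of those 14 fits. tgm5l, ADCY8 and ifi44f5 did not pass without wild-type H replicates 6 and 7 (adjusted p = 0.0976, 0.0588 and 0.0616), nor did ADCY8 have enough counts to be tested with the M libraries alone.

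**Figure D2:**
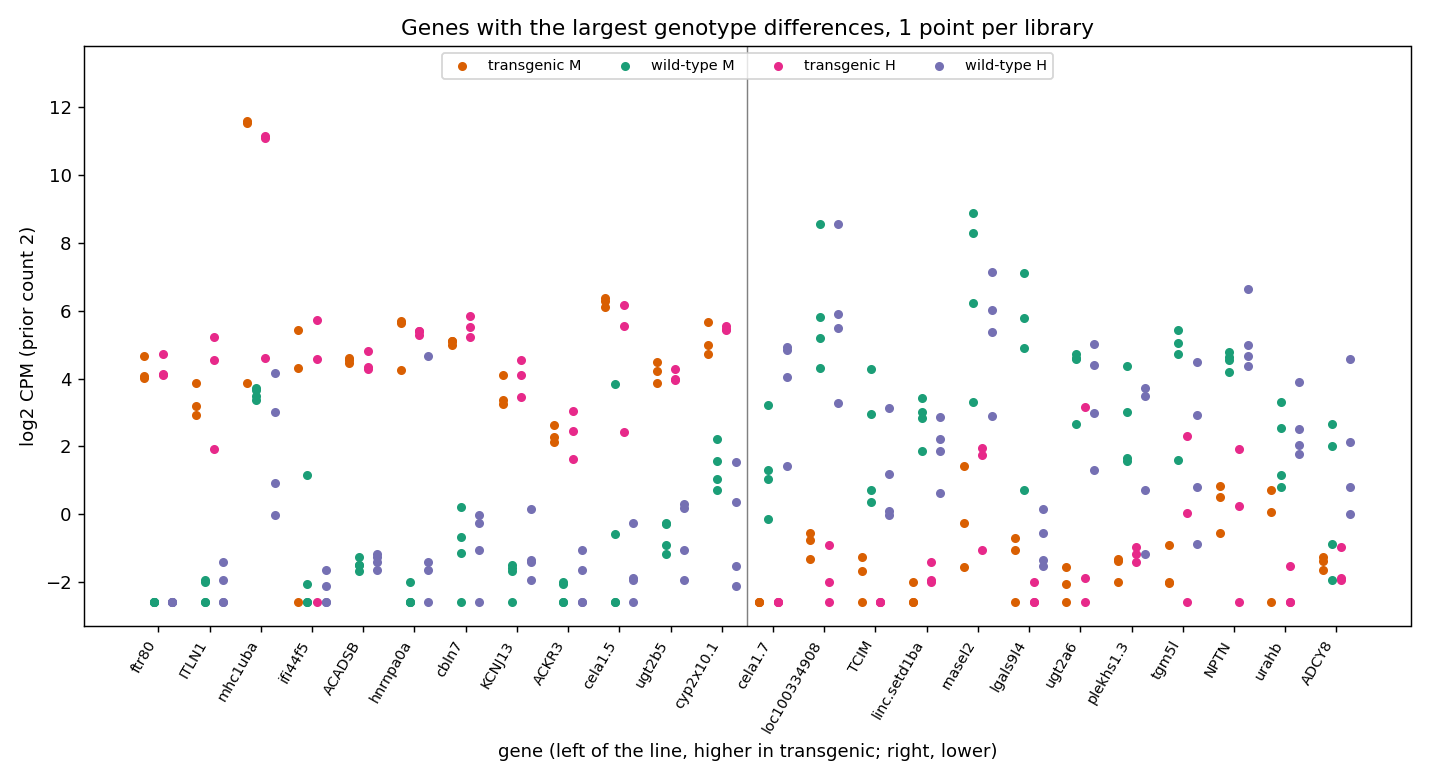
Log2 CPM of the 24 genes named for genotype in each of the 14 libraries, with 1 point per library and a colour per group, on a vertical axis of log2 CPM. Genes left of the line were higher and genes right of it lower in transgenic fish, and ftr80 lies at -2.58, the value of 0 counts, in all 8 wild-type libraries.

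Without wild-type H replicates 6 and 7, 715 genes rose and 759 fell, 1474 of 18697 tested, and 367 of the genes that rose and 331 of those that fell were shared with the fit of all libraries. Leaving out single libraries gave 1435 genes without wild-type H replicate 6, and 483, 490, 520 and 504 without transgenic M replicates 9, 10 and 11 and transgenic H replicate 16. DESeq2 called 1772 genes. The transgenic and wild-type libraries did not overlap for 3.72% of all tested genes, where chance gives 0.0666%. They did not overlap for 456 of the 784 genes, a share raised by the selection of these genes in the same libraries. Of the 784 genes, 334 had no symbol or a clone-type one.

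Of the 188 genes that differed by at least 8-fold with no overlap between genotypes, 27 lay within 100 consecutive tested genes in the order of the count table, where 40 genes passed in all. Of the 27, 9 were higher and 18 lower in transgenic fish, and they included cela1.7, rnasel2 and loc100334908. Random draws of 188 tested genes put at most 9 in any such window, and the 188 genes ranked first for H against M put 13. This test was chosen after the result was seen.

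**Figure D3:**
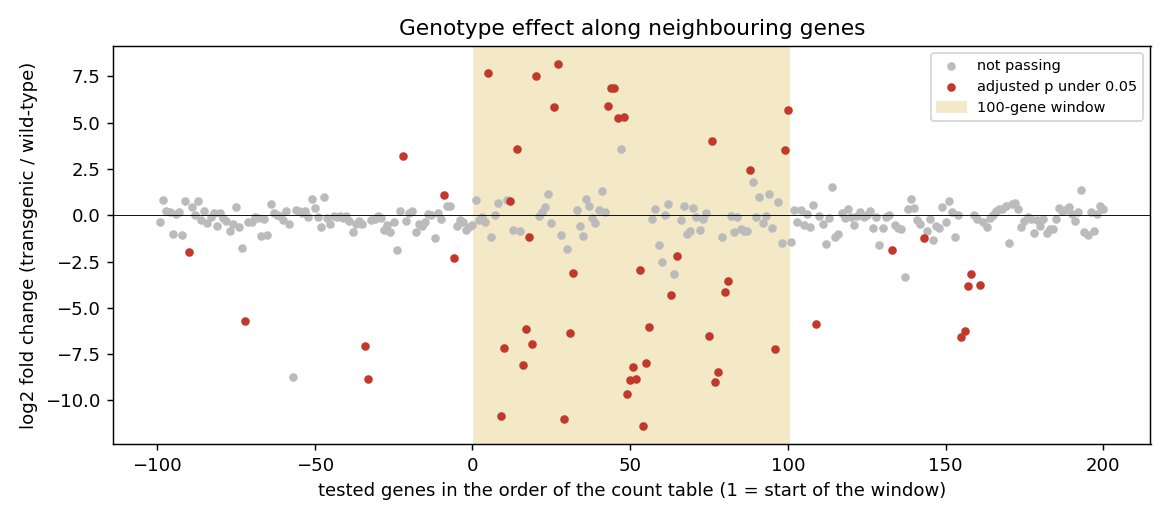
Genotype log2 fold change along 300 tested genes in the order of the count table, around the 100-gene window, with 1 point per gene and genes that passed marked. The window holds 27 genes of at least 8-fold with no overlap between genotypes, 9 higher and 18 lower.

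Barrier genes were examined next, since intestinal integrity is part of the question. None of the 23 tested claudins, the sealing and pore-forming proteins of tight junctions, passed in edgeR or limma-voom, 1 passed in DESeq2, and 1 had an unadjusted p under 0.05 in edgeR. A positive log2 fold change was found for 8 of them (list adjusted p = 0.882). The claudins with the smallest p were CLDN5 (ENSDARG00000014059), at -1.61 (SE 0.57, adjusted p = 0.153), and cldn7b, at -1.53 (SE 0.73, adjusted p = 0.270). Without wild-type H replicates 6 and 7, cldn7b was at -0.15. Of 33 other tight junction proteins, 1 passed: crb3a, a polarity protein of the apical membrane, rose from 22.9 ± 10.8 to 43.8 ± 4.88 CPM (log2 fold change 1.03, SE 0.26, adjusted p = 0.0426; list adjusted p = 0.636), and 0 passed when adjusted over the list alone. It passed without wild-type H replicates 6 and 7 (0.86, SE 0.15, adjusted p = 0.00598), did not pass with the M libraries alone (0.42, SE 0.16, adjusted p = 0.207), and passed in 2 of the 14 fits that left out 1 library. For adherens junctions and desmosomes, 0 of 22 genes passed in edgeR and 2 in DESeq2, with 4 at unadjusted p under 0.05 in edgeR (list adjusted p = 0.153), and the adhesion molecules epcam and nectin3b were at -1.88 and -2.44 (adjusted p = 0.181 and 0.209), against -0.36 and -0.70 without wild-type H replicates 6 and 7.

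Amino acid transporters are also part of the question. The basolateral and general carriers were higher as a list in transgenic fish (24 tested, 17 with a positive log2 fold change, median 0.60, adjusted p = 0.0259), but not with an estimated correlation (adjusted p = 0.914). This list mixes carriers of the basolateral membrane with general ones such as SLC38A2, so it does not measure export to the blood alone. The call was kept in 12 of 19 alternatives, with adjusted p up to 0.0790 when single libraries were left out. Over all genes 0 members passed in edgeR, with 8 at unadjusted p under 0.05, and 5 in DESeq2. In edgeR 4 rose when adjusted over the list alone. SLC43A2 (ENSDARG00000036848), a carrier of neutral amino acids, was at 0.96 (SE 0.27, adjusted p = 0.0691) and SLC38A2, a sodium-coupled glutamine carrier, at 0.80 (SE 0.24, adjusted p = 0.0897). With the M libraries alone 3 carriers rose: the aromatic amino acid exporter SLC16A10 (0.96, SE 0.16, adjusted p = 0.0186), the cationic exchanger subunit SLC7A7 (0.93, SE 0.17, adjusted p = 0.0235) and SLC43A2 (1.72, SE 0.35, adjusted p = 0.0381). The list was higher there too (adjusted p = 0.00138; adjusted p = 0.694 with an estimated correlation). Among the wild-type M libraries, replicate 2 had the lowest and replicate 3 the highest mean log2 CPM for both these carriers (3.29 and 4.36) and exocrine pancreas genes (5.11 and 9.57), against 4.69 to 4.87 and 8.70 to 8.95 in the transgenic M libraries. Within M in the joint fit of all libraries the adjusted p of these 3 genes was 0.685, 0.989 and 0.0583, and within H their log2 fold changes were 1.16, 1.03 and 0.19 (adjusted p = 0.169, 0.341 and 0.758). SLC16A10 and SLC7A7 were named after their values were seen.

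Apical amino acid and peptide carriers were not called over all libraries (19 tested, adjusted p = 0.198, median -0.03, mean 0.27, camera direction up). SLC1A4 was at -1.38 (SE 0.38, adjusted p = 0.0604). cltrn, collectrin, which brings neutral amino acid carriers to the surface, was at 3.81 (SE 1.2, adjusted p = 0.107), and rose with the M libraries alone (5.73, SE 1.12, adjusted p = 0.0320). slc36a4, named after its values were seen, fell without wild-type H replicates 6 and 7 (-0.75, SE 0.17, adjusted p = 0.0227). It was at -0.62 with the M libraries alone (adjusted p = 0.0890). In that last fit the apical list was higher (adjusted p = 0.0433; adjusted p = 0.694 with an estimated correlation), with 6 members higher and 1 lower when adjusted over the list alone. Among 37 ion channels, pumps and exchangers, the chloride channel clcn2c fell by 4.03 (SE 1.02, adjusted p = 0.0430), from 18 ± 41.2 to 0.425 ± 0.188 CPM, and it did not pass without wild-type H replicates 6 and 7 (adjusted p = 0.0618) and passed in 3 of the 14 fits that left out 1 library. That list was not called (adjusted p = 0.237), 0 members passed when adjusted over the list alone, and its median of -0.06 and mean of -0.13 had the opposite sign to camera's direction. slc26a6 (ENSDARG00000097292), an anion exchanger, and SLC4A4 (ENSDARG00000044808), a bicarbonate cotransporter, both named after their values were seen, rose without those 2 libraries (2.08, SE 0.41, adjusted p = 0.0119, and 0.98, SE 0.14, adjusted p = 0.00229) and with the M libraries alone (2.08 and 0.94, adjusted p = 0.0395 and 0.0221). The carbonic anhydrase gene ca4b, named in the same way, fell without those 2 libraries (-0.73, SE 0.19, adjusted p = 0.0375), and was at -0.97 with the M libraries alone (adjusted p = 0.0725).

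Lists of nutrient metabolism were called by camera in both directions. Chance cannot be excluded for the list calls by genotype, since 52 of 100 groupings of the libraries, the real one included, gave as many. Lipid absorption and lipoprotein genes were higher (29 tested, 26 positive, median 0.74, adjusted p = 0.000380; adjusted p = 0.914 with an estimated correlation), with 1 member passing, the fatty acid binding protein FABP1 (ENSDARG00000019357), which rose from 0.903 ± 0.857 to 10.6 ± 5.67 CPM (log2 fold change 3.57, SE 0.79, adjusted p = 0.0228). Genes of gluconeogenesis and fatty acid oxidation were higher (25 tested, 23 positive, median 0.34, adjusted p = 0.000613; adjusted p = 0.914 with an estimated correlation), with CPT1B at 2.62 (SE 0.78, adjusted p = 0.0857) and PDK4, which restrains glucose oxidation, at 1.55 (SE 0.50, adjusted p = 0.114). Cholesterol synthesis genes were lower (24 tested, 3 positive, median -0.71, adjusted p = 0.000846; adjusted p = 0.914 with an estimated correlation). STARD4, a sterol carrier, fell by 1.53 (SE 0.38, adjusted p = 0.0364), from 34.2 ± 15.6 to 11.8 ± 1.01 CPM, a call that held in 2 of the 14 fits that left out 1 library, against 8 for FABP1 (ENSDARG00000019357). Cholesterol synthesis was also lower without wild-type H replicates 6 and 7 (adjusted p = 5.37e-05; adjusted p = 0.934 with an estimated correlation) and with the M libraries alone (adjusted p = 1.01e-07; adjusted p = 0.749 with an estimated correlation), where 14 of 24 members fell when adjusted over the list alone. The lipid and fatty acid oxidation lists were not called without those 2 libraries (adjusted p = 0.432 and 0.119), in which enterocyte markers were low. ACSL1 of the lipid list, an acyl-CoA synthetase named after its values were seen, fell without these libraries (adjusted p = 0.0212).

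The brush-border list itself was higher in transgenic fish (22 tested, 19 positive, median 0.39, adjusted p = 0.00598; adjusted p = 0.914 with an estimated correlation), and turned to lower, without a call, once wild-type H replicates 6 and 7 were left out (adjusted p = 0.772). The call was kept in 13 of 19 alternatives, with adjusted p up to 0.0887 when single libraries were left out. SLC2A2, the basolateral glucose carrier, was at 1.11 (SE 0.38, adjusted p = 0.141) over all libraries and rose without those 2 (0.76, SE 0.14, adjusted p = 0.00969), while ggt1a was at -2.69 (adjusted p = 0.189). Of 13 goblet cell genes 0 passed in edgeR, with 6 at unadjusted p under 0.05, and 4 in DESeq2 (list adjusted p = 0.707, median 0.17, mean -0.23), and 3 were higher and 3 lower when adjusted over the list alone. sytl2b, a secretory granule protein, was at 1.12 (SE 0.31, adjusted p = 0.0666), and rose without those 2 libraries (0.93, SE 0.15, adjusted p = 0.00408). Genes of lysosome-rich enterocytes, enteroendocrine cells and smooth muscle were not called (adjusted p = 0.153, 0.175 and 0.468), nor were enteric neurons (adjusted p = 0.308), a list that was higher with the M libraries alone (adjusted p = 0.000866; adjusted p = 0.749 with an estimated correlation). Its member SLC18A3 (ENSDARG00000006356), the acetylcholine vesicle transporter, fell over all libraries by 2.65 (SE 0.65, adjusted p = 0.0362), and passed in 3 of the 11 fits without 1 library that tested it. Smooth muscle genes were lower without wild-type H replicates 6 and 7 (median -0.40, adjusted p = 0.00338; adjusted p = 0.934 with an estimated correlation).

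The list of cytokines and chemokines was called lower in transgenic fish, with a median of -0.72 (29 tested, 5 positive, adjusted p = 0.0307; adjusted p = 0.914 with an estimated correlation). The call was kept in 13 of 19 alternatives, with adjusted p up to 0.153 when single libraries were left out. Of its members 2 fell over all genes, or 5 when adjusted over the list alone. tnfa, a central inflammatory cytokine, fell by 1.45 (SE 0.35, adjusted p = 0.0330), and cxcl8a, a neutrophil attractant, by 2.13 (SE 0.54, adjusted p = 0.0440), from 34 ± 29.0 to 7.86 ± 3.71 CPM. Among 33 myeloid genes the matrix proteases MMP9 and mmp13a fell by 3.24 and 4.03 (SE 0.77 and 1.02, adjusted p = 0.0313 and 0.0422), and MFAP4 (ENSDARG00000111491) rose by 2.63 (SE 0.53, adjusted p = 0.0130; list adjusted p = 0.919). The calls of cxcl8a, MMP9 and mmp13a were lost without wild-type H replicates 6 and 7 (adjusted p = 0.0591, 0.0631 and 0.0843), and that of tnfa held (adjusted p = 0.0412). Of 31 interferon response genes 1 rose, mhc1uba, and 3 fell: mhc1zba, the antiviral GTPase mxe (-2.78, SE 0.60, adjusted p = 0.0204) and ifit9 (-2.52, SE 0.65, adjusted p = 0.0454). That list was not called over all libraries (adjusted p = 0.651), and was lower without the same 2 libraries (adjusted p = 0.0178; adjusted p = 0.934 with an estimated correlation) and with the M libraries alone (adjusted p = 0.000281; adjusted p = 0.749 with an estimated correlation), where wild-type M replicate 2 had the highest list mean of any library, a log2 CPM of 6.50. T and B lymphocyte genes were not called (adjusted p = 0.468). With single libraries left out, tnfa, cxcl8a, MMP9, mmp13a, mxe and ifit9 passed in 5, 3, 5, 5, 9 and 2 of 14 fits, and mhc1zba in all 14.

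The next 6 lists were called by camera, each with an adjusted p of 0.914 with an estimated correlation. Antimicrobial and acute-phase genes were higher (16 tested, median 0.86, adjusted p = 0.0378). Their call was kept in 6 of 19 alternatives, with adjusted p up to 0.347 when single libraries were left out. Liver (33 tested, median 0.91, adjusted p = 0.000846) and vitellogenin genes (8 tested, median 1.38, adjusted p = 0.000285) were also higher. Ovary and oocyte genes were lower (21 tested, median -3.40, adjusted p = 0.000128), as were testis (8 tested, with DAZL also on the ovary list, adjusted p = 0.0307) and cell cycle genes (34 tested, median -0.86, adjusted p = 0.0259). These last 2 calls were kept in 10 of 18 and 10 of 19 alternatives. No member of these 6 lists passed in edgeR, where 1, 0, 0, 2, 1 and 11 members in the same order had an unadjusted p under 0.05, and 0, 0, 2, 2, 1 and 5 passed in DESeq2. The ovary, testis and cell cycle lists were highest in wild-type H replicate 6, at mean log2 CPM of 9.51, 5.55 and 7.23, and were not called without wild-type H replicates 6 and 7 (adjusted p = 0.0755, 0.381 and 0.984), where the cell cycle list turned to higher. Exocrine pancreas genes were called higher (27 tested, adjusted p = 0.0182; adjusted p = 0.914 with an estimated correlation), with a median of 0.12 but a mean of -0.08. The unfolded protein response list was lower (27 tested, median -0.60, adjusted p = 0.0307; adjusted p = 0.914 with an estimated correlation). This call was kept in 10 of 19 alternatives, as was that of the exocrine pancreas. The chaperone CALR fell by 0.93 (SE 0.21, adjusted p = 0.0222, and under 0.05 in 10 of the 14 fits that left out 1 library). The circadian list was called higher (35 tested, median 0.12, adjusted p = 0.0477; adjusted p = 0.914 with an estimated correlation). The call was kept in 6 of 19 alternatives, with adjusted p up to 0.299 when single libraries were left out. The list turned to lower, without a call, without the 4 libraries with oocyte transcripts (adjusted p = 0.452). Its genes that passed were the cryptochrome cry3b, up by 0.86 (SE 0.16, adjusted p = 0.00980), and cry5, down at -1.25 (SE 0.26, adjusted p = 0.0166, and 0.0530 without transgenic M replicate 9).

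The remaining lists were not called by genotype. The extracellular matrix list had an adjusted p of 0.155, and fibronectin FN1 (ENSDARG00000019815) fell by 2.79 (SE 0.63, adjusted p = 0.0253), and passed in 8 of the 14 fits that left out 1 library. Respiratory chain genes had an adjusted p of 0.468, and ndufa9b, a subunit of complex I, rose by 5.50 (SE 0.44, adjusted p = 3.32e-05), to 3.12 ± 0.988 CPM. In the pigment cell list (adjusted p = 0.887), ALX4 (ENSDARG00000088332) had 1 count in the 6 transgenic and 52 in the 8 wild-type libraries, a ratio of 37.9 (counting interval 6.50 to 1524, adjusted p = 0.0389), and passed in 2 of the 11 fits without 1 library that tested it. Ribosomal proteins, red blood cells, skeletal muscle, endocrine pancreas, heat shock and glucocorticoid response, and the growth hormone axis had adjusted p of 0.204, 0.887, 0.204, 0.181, 0.574 and 0.0895. Without wild-type H replicates 6 and 7, ribosomal protein and respiratory chain genes were lower (adjusted p = 4.05e-05 and 0.00338) and the growth hormone axis higher (adjusted p = 0.0333), each with adjusted p = 0.934 with an estimated correlation. Camera gave up as the direction for red blood cells, lymphocytes and myeloid cells, whose medians were -0.23, -0.03 and -0.09, and down for the melanocortin list, whose median was 0.03.

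Within the M libraries, which held neither oocyte nor vitellogenin transcripts above 0.00104% of counts, 95 genes rose and 83 fell in transgenic fish. hnrnpa0a, an RNA-binding protein, had 1539 counts in the 3 transgenic and 1 in the 4 wild-type libraries, a ratio of 1907 (counting interval 342 to 75356, adjusted p = 0.0439), ftr80 was at least 307-fold higher (adjusted p = 0.00106) and ITLN1 (ENSDARG00000095082) 247-fold (counting interval 67.8 to 2043, adjusted p = 0.00396). ACADSB (ENSDARG00000098174), KCNJ13 and cbln7 rose by 6.84, 6.49 and 6.21 (SE 0.33, 0.77 and 0.85, adjusted p at most 0.00396). loc100334908, lgals9l4, crp5, a C-reactive protein gene, mhc1zba and ugt2a7 fell by 8.26, 7.72, 6.88, 4.38 and 3.84 (adjusted p between 0.0243 and 0.0362), and linc.setd1ba had 1 count in transgenic fish, 275-fold lower (counting interval 49.1 to 10903, adjusted p = 0.00201). Of these 12 genes hnrnpa0a, loc100334908, lgals9l4, crp5, mhc1zba and ugt2a7 lost their calls in 6 or more of the 14 fits that left out 1 library. With the 7 M libraries fitted alone 742 genes passed, 378 higher and 364 lower of 17177 tested, and 722 passed in the joint fit without wild-type H replicates 6 and 7. The joint count was 486 without wild-type H replicate 6, and 63, 80 and 69 without transgenic M replicates 9, 10 and 11. Without wild-type M replicates 1, 2, 3 and 4 it was 100, 95, 88 and 84.

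Within the H libraries 133 genes rose and 81 fell. ftr80 was at least 329.6-fold higher (adjusted p = 0.00108), gig2i, a gene of the grass carp reovirus-induced family, at least 83.3-fold (adjusted p = 0.000565), and ITLN1 (ENSDARG00000095082) 368-fold (counting interval 126 to 1791, adjusted p = 0.00222). ACADSB (ENSDARG00000098174), cbln7 and the thyroglobulin gene TG rose by 6.61, 6.60 and 5.56 (SE 0.32, 0.85 and 1.09, adjusted p = 5.77e-07, 0.00255 and 0.0301). cela1.7 was at least 231-fold lower (adjusted p = 0.0341), and urahb, a urate pathway enzyme, and FSTL5 had 2 and 3 counts in transgenic fish, 108-fold and 59.8-fold lower (counting intervals 29.7 to 895 and 20.2 to 292, adjusted p = 0.0461 for both). loc100334908, gpc2 and NPTN (ENSDARG00000103002) fell by 9.55, 5.58 and 4.81 (SE 1.83, 1.01 and 1.01, adjusted p = 0.0262, 0.0185 and 0.0418). TG, cela1.7 and urahb did not pass without wild-type H replicates 6 and 7 (adjusted p = 0.114, 0.0846 and 0.0860), and FSTL5 was not tested there. With single libraries left out, TG, loc100334908 and gpc2 passed in 11 of 14 fits each, cela1.7 in 7, NPTN (ENSDARG00000103002) in 4 and urahb in 3, and FSTL5 in 1 of the 11 that tested it. The fit without those 2 libraries called 372 genes, and the 7 H libraries fitted alone called 11. The joint count was 1034 without wild-type H replicate 5 and 474 without wild-type H replicate 6. It was 137, 141, 85, 95 and 77 without wild-type H replicate 7, transgenic M replicate 9 and transgenic H replicates 13, 14 and 16.

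The genotype effect was then compared between the letters. No gene had an effect that differed between M and H in edgeR (0 of 18619, 1285 at unadjusted p under 0.05), against 24 in DESeq2, 0 in limma-voom and 1 or 2 with limma-trend on FPKM. gig2i, which passed in H, was at 1.37 in M (adjusted p = 0.262). Fitted separately, the M libraries and the H libraries without wild-type H replicates 6 and 7 shared 26 genes that rose, where independent lists of 369 and 47 genes among 16782 would share 1.03, and 23 that fell, where 0.624 would be shared. Of the genes called in both, 0 went in opposite directions. These fits have no library in common. In the joint fit without those 2 libraries, 777 of the 780 genes called by genotype over all libraries had the same sign in M and H (99.6%), a share that is raised by their selection on the average of both.

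**Figure D4:**
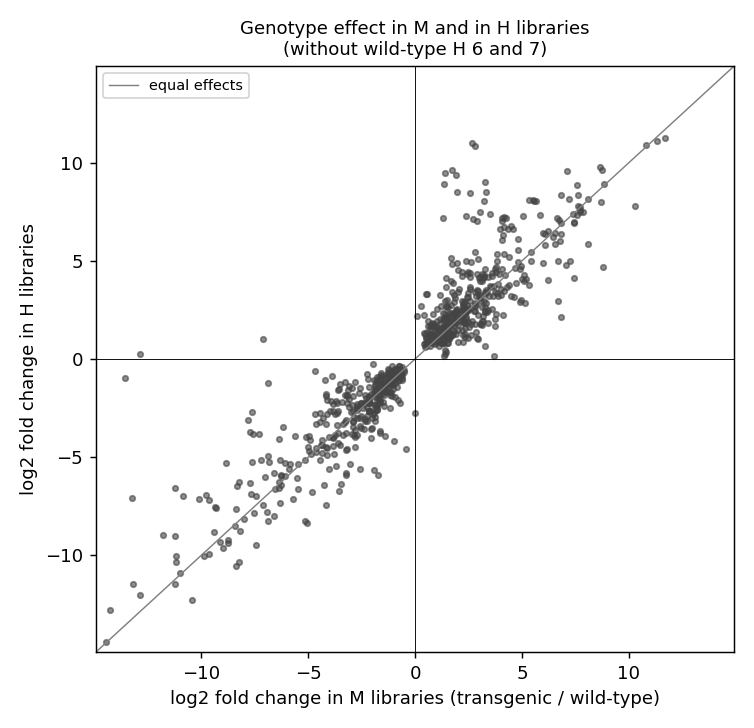
Genotype log2 fold change in M (horizontal axis) against H (vertical axis) for the 780 genes called by genotype, in the fit without wild-type H replicates 6 and 7, with 1 point per gene. The signs are the same for 777 genes, which were selected by a test that averages both letters.

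H was compared with M libraries over both genotypes. Oocyte and yolk transcripts were high in some H libraries and low in others: the ovary list had a mean log2 CPM of -0.91, -1.65 and -2.14 in wild-type H replicate 5 and transgenic H replicates 14 and 16, and vitellogenins made up at most 0.00201% of counts in wild-type H replicates 5, 6 and 7. No single gene passed in edgeR (0 of 18619, 1449 at unadjusted p under 0.05), against 344 in DESeq2, 0 in limma-voom and 2 or 3 with limma-trend on FPKM. Without wild-type H replicate 5, 173 genes passed, of which 170 were higher in H, and 1 and 3 passed without transgenic H replicate 14 and wild-type H replicate 8. vtg1 was at a log2 fold change of 16.03 (SE 3.18) and vtg3 at 11.91 (SE 2.15), and the egg coat gene zp3b and the claudin cldnd were at 9.15 (SE 1.74) and 9.52 (SE 1.89), each with adjusted p = 0.178. As lists, vitellogenins (8 tested, adjusted p = 1.69e-18; adjusted p = 0.227 with an estimated correlation) and ovary genes (21 tested, adjusted p = 1.62e-25; adjusted p = 0.490 with an estimated correlation) were higher in H, and all 8 and all 21 passed when adjusted over the list alone. Testis genes (8 tested, 6 adjusted over the list alone, adjusted p = 4.1e-06; adjusted p = 0.655 with an estimated correlation), which share the germ cell gene DAZL, at 8.75 (SE 2.05, adjusted p = 0.196), with the ovary list, and cell cycle genes (34 tested, 8 adjusted over the list alone, adjusted p = 6.37e-06; adjusted p = 0.724 with an estimated correlation) were also higher. Without the 4 libraries with oocyte transcripts both turned to lower in H, testis without a call (adjusted p = 0.499; adjusted p = 0.844 with an estimated correlation) and cell cycle with one (adjusted p = 8.69e-05; adjusted p = 0.741 with an estimated correlation).

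Lists of gut wall and enterocyte function were called lower in H over all libraries. Smooth muscle, interferon response and respiratory chain genes had medians of -0.54, -0.53 and -0.24 (adjusted p = 1.36e-07 for each; adjusted p = 0.724, 0.724 and 0.738 with an estimated correlation). Brush-border, lipid absorption and fatty acid oxidation genes had medians of -0.39, -0.38 and -0.35 (adjusted p = 1.52e-05, 1.56e-05 and 3.35e-05; adjusted p = 0.724 for each with an estimated correlation). Enteroendocrine, lysosome-rich enterocyte and apical amino acid carrier genes followed (adjusted p = 0.000137, 0.000629 and 0.00107; adjusted p = 0.724 for each with an estimated correlation). Ribosomal protein, skeletal muscle, circadian and enteric neuron genes completed the 13 lower lists (adjusted p = 0.00871, 0.0153, 0.0398 and 0.0439; adjusted p from 0.738 to 0.930 with an estimated correlation), with calls kept in 10, 11, 6 and 8 of 18 alternatives. Wild-type H replicates 6 and 7 had the lowest brush-border values, and without them the brush-border, lipid absorption, fatty acid oxidation and apical carrier lists were not called (adjusted p = 0.552, 0.744, 0.273 and 0.918), nor were cell cycle genes (adjusted p = 0.430), while ribosomal proteins turned to higher in H (adjusted p = 3.24e-11; adjusted p = 0.781 with an estimated correlation). Smooth muscle and enteroendocrine genes were lower there too (adjusted p = 1.86e-10 and 0.000114; adjusted p = 0.579 for each with an estimated correlation). Without the 4 libraries with oocyte transcripts, circadian and lipid absorption genes also turned to higher in H (adjusted p = 0.00491 and 0.0447; adjusted p = 0.741 and 0.760 with an estimated correlation). Brush-border and apical carrier genes turned there without a call (adjusted p = 0.0828 and 0.395). The directional fry test called 1 list, the vitellogenins (adjusted p = 0.0352).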

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

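Of the tests in this part, those of depth and genotype for the oocyte transcripts, of the 100-gene window, of oocyte and liver transcripts as a source of the genotype differences, and all 3 on vitellogenins were chosen after the result was seen. Among 126 sets of values examined within groups of 4, 11 had 1 library far from the other 3, where chance alone gives about 1 in 20, or 6.3. That rate assumes independent values away from 0 counts. The sets share libraries, and some, such as hnrnpa0a in wild-type M, lie near 0 counts, so 6.3 is only a rough guide. Wild-type M replicate 2 stood apart in 5 of the 11. Its mean log2 CPM was 2.21 for claudins (2.94 to 3.01 in the other 3 libraries) and 4.13 for circadian genes (4.62 to 4.68). Its log2 CPM was 1.14 for ifi44f5 (-2.58 to -2.06), -2.58 for KCNJ13 (-1.68 to -1.5) and 2.65 for ugt2a6 (4.57 to 4.72). Wild-type H replicate 6 was at 3.33 for smooth muscle genes (5.63 to 5.92) and 1.52 for interferon response genes (4.13 to 4.63). Wild-type M replicate 4 was at -1.03 for testis genes (-1.98 to -1.85), and wild-type H replicate 8 at 3.42 for antimicrobial genes (4.93 to 5.02). hnrnpa0a was at -2.0 in wild-type M replicate 3, where the others had no counts (-2.58), and at 4.67 in wild-type H replicate 7 (-2.58 to -1.40).

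Oocyte transcripts stood out in 4 H libraries. Depth is argued against, since the 10771787 counts of wild-type H replicate 6 lie inside the range of the other libraries, and genotype alone is argued against, since transgenic H replicate 13 lay 5.48 above the highest M library on the log2 scale. Ovary tissue in the dissected sample is a candidate explanation: of 436 genes outside the oocyte list that were at least 50-fold higher in wild-type H replicate 6 than in the median M library, 72.0%, 96.3% and 87.2% lay over 2-fold above every M library in transgenic H replicate 13 and wild-type H replicates 7 and 8. In transgenic H replicates 14 and 16 and wild-type H replicate 5 those shares were 2.06% to 10.6%.

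Large genotype differences with no overlap between libraries were found for 188 genes. Oocyte or liver transcripts in the H libraries are argued against as their source, since of 305 such genes chosen by the H libraries alone, 185 (60.7%, Wilson 95% interval 55.1% to 66.0%) had no overlap in the same direction in M, where chance gives 2.86%, and 1 had none in the opposite direction. The site of the transgene alone is also argued against, since the 178 genes that could be placed lay on 25 chromosomes. Chromosome 22 held the most, 21.9% of them against 4.08% of all placed tested genes, so a linked site may account for part. A segment of another haplotype in the transgenic line may also account for part of them. Of the 188 genes, 27 lay within 100 consecutive tested genes. Random draws, 10000 in all, gave at most 9, and genes ranked first by H against M gave 13. Chromosome 22 held 39 of the placed genes and the next, chromosome 7, held 11, so the 27 genes probably make up much of the excess on chromosome 22. The count on that chromosome and the count in the window are therefore not separate evidence, and cannot tell a linked site from such a segment. Whether inherited differences between fish stocks in linked blocks account for more stays open: 40.4% had another such gene among the 5 nearest on each side (Wilson 95% interval 33.7% to 47.6%; random median 9.57%, permutation p = 0.0001, the smallest these draws can give), but outside that window 31.1% did, against 36.7% of genes ranked first by H against M and 43.1% of the 596 other genes called by genotype, a larger set. The Wilson intervals treat genes as independent, which neighbours measured in the same libraries are not, and may be too narrow. An effect of the transgene also stays open, and loss of reads of a diverged haplotype in mapping was not tested.

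Vitellogenin transcripts were abundant in 4 H libraries. Liver tissue carried over in the dissection stays open as a source: 6 M libraries had a liver list at or above the lowest of these 4 with under a hundredth of their vitellogenin share, but if only H fish were females, this says nothing about liver in H. Among the H libraries, liver list means were 9.59, 6.08 and 9.42 log2 CPM in transgenic replicates 13, 14 and 16. Wild-type H replicate 8 was at 4.94. Wild-type H replicates 5, 6 and 7 were at 6.40, 7.04 and 6.11, with vitellogenins at most 0.00201% of counts. The liver list alone therefore did not set the vitellogenin share in H, but whether all H fish made yolk is not known. Genotype within the H libraries stays open, with 3 of 3 transgenic and 1 of 4 wild-type libraries (Fisher's exact test, two-sided p = 0.143, where the smallest possible is 0.0286). The letter H may mark female fish, which the labels do not say: 6 of 7 H and 0 of 7 M libraries held vitellogenin or oocyte transcripts (Fisher's exact test, two-sided p = 0.00466).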

How the results depend on the processing

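Chosen after seeing the data were the fits without wild-type H replicates 6 and 7, without these and wild-type H replicate 8 and transgenic H replicate 13 (the 4 with oocyte transcripts), with the ovary list as covariate, and the list tests with the M libraries alone. No paired analysis was possible because the groups share no replicate numbers. Unless a construction with fewer libraries shows it, the cause was not tested. The 69 named genes that passed kept direction and call in 1597 of 2081 pairs of gene and setting, lost the call in 484 and reversed in 0, and other scalings moved the median of all genes by at most 0.0514. For genotype, 784 genes became 1772 with DESeq2, 1659 with 2 surrogate variables, 1474 without wild-type H replicates 6 and 7, and 483 (without transgenic M replicate 9) to 1435 (without wild-type H replicate 6) with single libraries left out. Within M, 178 became 593 with DESeq2, 305 with FPKM of every gene, 742 with the M libraries alone, 722 and 602 without the 2 and the 4 libraries, 279 with the ovary covariate, and 63 to 486 with single libraries left out. Within H, 214 became 2144 with DESeq2, 11 with the H libraries alone, 372 and 123 without the 2 and the 4 libraries, 124 with the ovary covariate, and 77 to 1034 with single libraries left out. The difference between letters, 0 in edgeR with 1285 at unadjusted p under 0.05, was 24 with DESeq2, 1 with FPKM at either pseudocount, 2 with FPKM of every gene, and 0 with each library left out. H against M, 0 with 1449 at unadjusted p under 0.05, was 344 with DESeq2, 3 with FPKM at either pseudocount, 2 with FPKM of every gene, and 0 to 173 with single libraries left out. The 15 lists called by genotype became 0 with an estimated correlation, 0 with fry, 6 without the 4 libraries, and 10 to 16 with single libraries left out. The 17 lists called for H against M became 0 and 1 with the same tests and 14 to 19 with single libraries left out. Reversed by genotype, with adjusted p, were brush-border genes (0.772 and 0.408 without the 2 and the 4), cell cycle (0.984 and 0.144), circadian genes (0.452 without the 4), enteric neurons (0.000866 with M alone) and ribosomal proteins (2.27e-07 with M alone, 4.05e-05 and 2.47e-09 without the 2 and the 4). Reversed for H against M without the 2 and the 4 were lymphocyte genes (0.0298 and 0.00562), the unfolded protein response (0.0155 and 0.00163), circadian genes (0.495 and 0.00491) and ribosomal proteins (3.24e-11 and 2.31e-24, and 1.69e-06 to 0.808 with single libraries left out, reversed without wild-type H replicate 6). Without the 4 alone, apical carriers (0.395), brush-border genes (0.0828), lipid absorption (0.0447), testis genes (0.499) and cell cycle genes (8.69e-05) reversed, and without transgenic H replicate 14 cholesterol synthesis did (0.0288, and 0.00811 to 0.992 with single libraries left out). The 14 of these reversals with adjusted p under 0.05 had adjusted p from 0.741 to 0.934 with an estimated correlation, and enteric neurons 0.749.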

Other observations

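The tests of other groupings of the libraries given below were planned, and the fits of the M libraries alone for gene lists were chosen after the result was seen. With the 7 M libraries alone, genes of lysosome-rich enterocytes, which take up and digest luminal protein, were higher in transgenic fish (21 tested, median 0.67, adjusted p = 0.000320; adjusted p = 0.749 with an estimated correlation). LGMN, the lysosomal protease legumain, rose by 1.22 (SE 0.17, adjusted p = 0.00807), and ctsl.1, a cathepsin L gene, by 2.23 (SE 0.42, adjusted p = 0.0277). Enzymes of cholesterol synthesis fell there: DHCR7 by 1.78, LSS by 1.46 and IDI1 by 1.44 (adjusted p = 0.0348, 0.0310 and 0.0274). Within H, LGMN was at 0.29 and ctsl.1 at -0.84 (adjusted p = 0.697 and 0.578), and the lysosome list had mean log2 CPM of 6.37, 3.95 and 5.97 in transgenic H replicates 13, 14 and 16 against 6.75, 3.41, 5.1 and 6.90 in wild-type H replicates 5 to 8. Without wild-type H replicates 6 and 7, ctsl.1 was at 0.25 over both letters (adjusted p = 0.736). In the joint fit of all libraries none of LGMN, ctsl.1, DHCR7, LSS and IDI1 passed within M (adjusted p from 0.391 to 0.711). pllp, of the same list as LGMN, fell without wild-type H replicates 6 and 7 (-0.55, adjusted p = 0.0355) and was at -0.39 with the M libraries alone (adjusted p = 0.304). These genes were named after their values were seen.

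In the same fit PDK4 rose by 1.76 (SE 0.30, adjusted p = 0.0188) and the receptor kinase gene ltk by 3.35 (SE 0.47, adjusted p = 0.00909), while SOCS1, a brake on cytokine signalling, fell by 1.36 (adjusted p = 0.0344) and irf9, a component of the interferon signalling complex, fell by 0.58 (adjusted p = 0.0440), all but PDK4 named after their values were seen. Within H, ltk and irf9 were at -0.39 and 0.19 (adjusted p = 0.812 and 0.820). Of the genes called by genotype, 403 were called in the same direction over all libraries, without wild-type H replicates 6 and 7, and with the M libraries alone, 199 higher and 204 lower.

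Other groupings of the libraries into sets of the same sizes were fitted to see whether chance can be excluded. For genotype, 1 of 100 groupings, the real one, gave 784 genes, and the highest other gave 74. Within M it was 1 of 35 (178 genes, highest other 7). Each is the smallest share that its groupings can give, and argues against chance. It does not separate the transgene from anything else that the libraries of a genotype share. Within H chance cannot be excluded, with 2 of 35, or 5.71% (214 genes, highest other 3062). That other grouping calls many times the real count and sets wild-type H replicates 6, 7 and 8 together, which points to a structure of the samples. For the difference between letters and for H against M the real count was 0 genes, so that each of the 100 groupings gave as many (100 of 100 in both cases, highest other 1), which says nothing about chance. For the gene lists chance cannot be excluded, with 52 of 100 by genotype (15 lists, highest other 24) and 35 of 100 by letter (17 lists, highest other 22).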
